A study of Rattus norvegicus with 6 samples.

How the data were processed

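The series holds 6 single-colour Cy3 Agilent arrays of whole heart RNA, 3 from animals given AACO and 3 from control animals. AACO is a Chinese medicine formula whose letters the labels do not explain. Per the labels' protocols, AACO solution at 0.386 µg/g or the same amount of double-distilled water was given daily for 8 weeks, and the animals were killed 24 h after the last dose. The dose and its unit are those of the labels, and nothing in the files allows a check of the unit. The series text says that the animals had TAC, in heart failure research the usual short name of transverse aortic constriction, and that different donors were used for each experiment. It calls the animals mice, while the sample labels give Rattus norvegicus and the array files place their probes on the rat genome build rn4, so the samples were treated as rat. Per the labels' protocols, RNA was prepared with a mirVana kit and 0.2 ug was amplified and labelled for each array.

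Per the file headers, each array was read with Agilent Feature Extraction 10.7.1.1, and the deposited intensity of a spot is its processed signal, which is background-corrected and not scaled between arrays. The deposited series matrix holds log2 values of the same arrays, whose processing the labels do not describe. Its columns correlated across probes with log2 of the scanner values at r between 0.998 and 0.99998, and every column had a median of 6.7708673, so the arrays had been normalized to a common centre. Its direction and log base were therefore taken as those of the scanner values, and the exact normalization stayed unknown. Genes called from it with AACO, 986 higher and 1001 lower, were close in number to those after quantile normalization, 991 and 1004. The alternatives with the series matrix and with quantile normalization are therefore not independent of each other.

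Control spots and spots with an outlier mark were left out, and spots of the same probe were averaged on the log2 scale. The values were log2 of the processed signal minus the 75th percentile of the array's non-control probes. Of 30367 non-control probes, 30357 had a value on every array, and 20112 were well above background on at least 3 of the 6 arrays and were kept. An accession matched the symbol table of the reference assembly for 17997 probes, with a symbol other than the array file's for 3333 of them, while 5156 probes kept the name in the array file and 7214 had only an accession or probe ID. A gene was represented by its probe of highest mean signal, which left 17536 genes tested, 13402 of them with a gene name. Among 2359 genes with more than 1 probe tested, 222 differed between the groups, and for 35 of these another probe moved the opposite way. No reference of build rn4 was available, so probe positions are those in the array files and the part of the gene they lie in is not given.

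AACO was compared with control in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided, Benjamini-Hochberg over all genes tested). A gene is said to have differed, risen or fallen where its adjusted p was under 0.05. Log2 fold changes are AACO minus control with their standard error, and every adjusted p of a gene is limma's with 3 arrays per group. The sample titles carry numbers, but whether these are animals' numbers is not stated, so p-values measure the spread between these 6 samples. Where no probe of a gene was well above background on any array of a group, the measured fold is only a bound. It was then given as at least the mean of the brighter group over the dimmer group's mean of, per array, the higher of the probe's own signal and the lowest signal of any probe well above background.

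The lists of genes were fixed before the data were examined. They covered, among others, hypertrophy and fetal genes, the adult sarcomere and calcium handling, cardiac ion channels, matrix and fibrosis, fatty acid oxidation, glycolysis, oxidative phosphorylation, inflammatory cytokines, the interferon response, antioxidant genes, apoptosis, the unfolded protein response, heat shock proteins, immediate early genes, the circadian clock, hypoxia, the cell cycle and glucocorticoid-responsive genes. Marker lists of 18 other cell types and tissues were fixed with them, from fibroblasts to thymus. Of 37 lists, 36 had at least 3 tested members and entered limma's camera test, which compares a list with all other genes at a preset correlation of 0.01 between genes, adjusted over the lists. The test was repeated with a correlation estimated for each list, and with fry, which asks whether the members of a list move, on balance, one way or, in its mixed form, in either direction. Counts adjusted over the list alone are given where they differ from those over all genes.

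The genes to be named were also set by a rule fixed in advance. It took the 8 named genes with the largest rise and the 8 with the largest fall among those that differed without overlap between the groups, the 2 members of each list with the smallest p, and 12 heart failure and inflammation genes whatever their values. Not every gene and list so chosen is reported. Any other gene named was chosen after its values were seen. Single measures of the arrays were compared by an exact two-sided permutation test, which with 3 against 3 cannot give a p below 0.1.

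The alternatives planned in advance were other scalings, normexp background correction with an offset of 50, the series matrix, other filters on dim probes, the mean of a gene's probes, other variance models, array weights, and leaving out each array in turn. The fit was tested on simulated data with the spread of the real arrays, in which 200 of the 17536 genes of the comparison were changed. It recovered 0 of 200 genes changed 1.5-fold, 102 changed 2-fold and 170 changed 4-fold, with 2.86% and 6.59% false calls at the latter folds. In the real comparison 1975 genes differed, so a larger unadjusted p sufficed for a call than with 200 changed genes. Genes changed less than 1.5-fold were called there, such as Mef2c (1.46-fold, limma adjusted p = 0.0285). These shares therefore do not give the power of the real comparison. The number of arrays limits the precision. On data simulated without change camera called 0 of 36 lists. The simulated genes varied independently of each other, while correlations estimated for the real lists reached 0.71 (fibroblast list). The simulation therefore does not test the preset correlation. Sex-linked genes could not be described, since the array holds 0 probes under the symbols Xist, Ddx3y, Kdm5d, Eif2s3y and Uty.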

Results

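Gene expression was measured in 3 samples, labelled as whole heart, of rats given AACO and 3 of rats given water for 8 weeks, after an operation that models heart failure. On the AACO arrays 71.8% ± 0.78 of spots (SD, n = 3) were well above background, against 67.5% ± 1.37 (n = 3) on the control arrays, and the groups did not overlap (exact permutation p = 0.1, the smallest possible). The median signal of non-control spots lay between 212 and 261 on the AACO arrays and between 143 and 204 on the control arrays. No non-control spot was saturated on any array. Over the genes tested, pairs of AACO arrays correlated at r between 0.9908 and 0.9944, pairs of control arrays at 0.9875 to 0.9911, and pairs across the groups at 0.9767 to 0.9875. The first principal component held 54.9% of the variance and separated the groups, with AACO replicate 3 at −15.5 between the other AACO arrays at −45.97 and −40.8 and the control arrays at 30.8 to 37.2. All AACO arrays lay on 1 slide scanned on 1 day and all control arrays on another slide scanned on another day, so batch and group cannot be told apart in any comparison below.

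The comparison of AACO with control asks which cardiac genes differ in heart failure animals treated with the formula. Of 12 macrophage markers 9 fell under AACO, among them the receptor gene Mrc1. The genes of the mitochondrial kinase Pdk4 and of the haem-degrading enzyme Hmox1 fell too. The clock gene Bmal1 fell and its output gene Dbp rose. The potassium channel gene Kcnh2 rose, and the matrix gene Ccn2 fell. The natriuretic peptide genes Nppa and Nppb and the myosin genes Myh6 and Myh7, the usual markers of hypertrophy and failure, did not differ at the adjusted threshold, though Nppb was among the genes at least 2-fold lower at an unadjusted p under 0.05. Myh6 and Myh7 read nearly alike on every array, and whether their probes tell these genes apart was not tested.

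In all, 1108 genes rose and 867 fell, which is 11.3% of the 17536 tested. Of these, 427 rose and 290 fell by at least 2-fold, and the median size of the change among the genes that differed was 0.84 on the log2 scale. Without adjustment, 5402 genes had p under 0.05, and 645 of them were at least 2-fold higher and 384 at least 2-fold lower. The values of the groups did not overlap for 6556 genes (37.4%, where chance gives 10%). The counts leaned on single arrays: 179 genes rose and 227 fell without AACO replicate 1, 108 and 148 without AACO replicate 2, 737 and 694 without control replicate 1, 713 and 496 without control replicate 2, and 322 and 304 without control replicate 3. Of the 56 genes named by the rule that differed, all 56 kept their direction in each of these fits, and 22, 15, 40, 36 and 29 of them still differed in the same order. Without AACO replicate 3, by contrast, 1225 genes rose and 937 fell, and 50 of the 56 still differed. AACO replicates 1 and 2 were also the arrays with high signal of Myl7 and Sln, transcripts of the atria. With the Myl7 and Sln level as a covariate, all 56 kept their direction and 0 still differed. How far the counts rest on atrial tissue in these replicates therefore cannot be told from these arrays. The share of rises among the genes that differed was 56.1%, and moved to 33.7% with normexp background correction, to 35.6% with no filter on dim probes, to 69.2% with spike-in scaling and to 95.9% with no scaling. Without scaling the median of all genes stood at 0.52 on the log2 scale, against 0.04 in the scaled values.

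**Figure D1:**
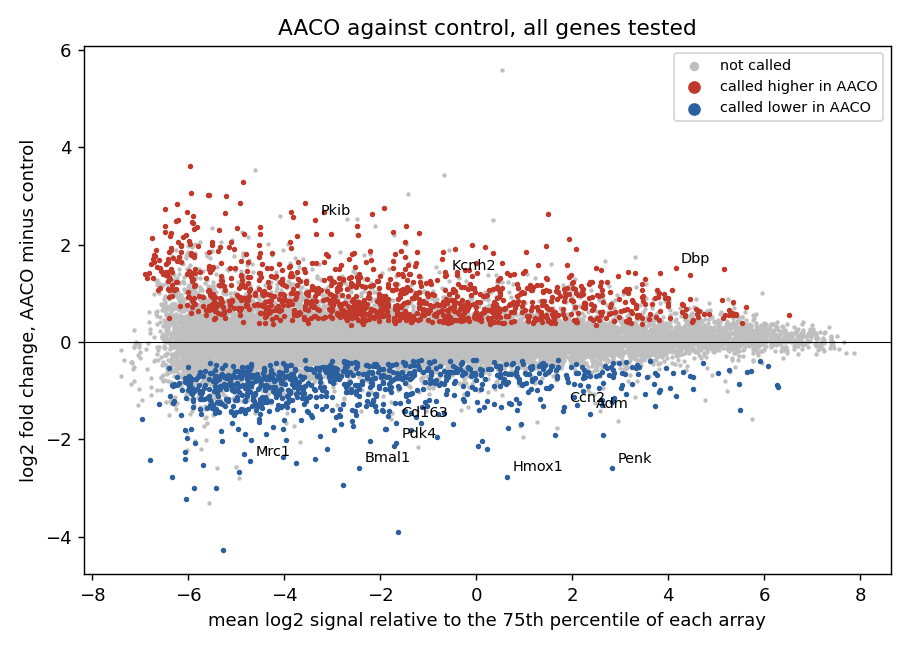
Log2 fold change of AACO against control (vertical axis) by mean normalized log2 signal (horizontal axis) for the 17536 genes tested. Coloured points are the 1108 genes that rose and the 867 that fell at a limma adjusted p under 0.05.

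Several of the genes with the largest fitted rises were measured only with AACO. The endothelin gene Edn2 was not well above background on any control array, so its rise was at least 3.14-fold (adjusted p = 0.00478; probe at chromosome 5, 140748047 to 140748106, rn4). The same held for the taste receptor gene Tas2r120 (at least 2.61-fold, adjusted p = 0.0165), the transcription factor gene Bcl11b (at least 3.36-fold, adjusted p = 0.0099), Phactr3 (at least 1.98-fold, adjusted p = 0.0108) and Arhgef19 (at least 2.29-fold, adjusted p = 0.0152). Among genes measured on all arrays, the cell death gene Bik rose 6.35-fold (log2 2.67 ± 0.37, adjusted p = 0.013) and the kinase inhibitor gene Pkib rose 5.68-fold (2.51 ± 0.23, adjusted p = 0.00694). Id3 rose by 2.64 ± 0.32 (adjusted p = 0.0104) and was above background on 1 of 3 control arrays.

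The largest fall with values on all arrays in both groups and a single direction across probes was that of Hmox1. Its mean was −0.74 ± 0.54 (SD, n = 3) with AACO and 2.03 ± 0.12 (n = 3) in control hearts, a log2 fold change of −2.77 ± 0.27 (adjusted p = 0.00697; chromosome 19, 13969336 to 13969395, rn4). Bmal1 changed by −2.59 ± 0.23 (adjusted p = 0.00635; chromosome 1, 171161969 to 171162028), and its other probe by −2.35. The opioid precursor gene Penk changed by −2.60 ± 0.55 (adjusted p = 0.0355). Cfap95 (−4.28 ± 0.71, adjusted p = 0.0196) and Rec8 (−3.00 ± 0.43, adjusted p = 0.0138) were above background on 1 of 3 AACO arrays each, and Shcbp1l (−2.66 ± 0.23, adjusted p = 0.00571) on 2 of 3. Upp2 was not well above background on any AACO array and was at least 3.91-fold lower (adjusted p = 0.0133). Nr4a3 fell by 3.91 on its brighter probe (adjusted p = 0.0431), while its other probe moved by 1.15. Its adjusted p lay between 0.0849 and 0.143 without any 1 of the arrays other than AACO replicate 3. Edn2, Hmox1, Bmal1, Pdk4, Mrc1, Ccn2 and Kcnh2 differed in each of the 6 fits that left out 1 array.

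Macrophage markers were lower with AACO. Mrc1, the mannose receptor gene, was 5.46-fold lower with AACO (log2 −2.45 ± 0.23, adjusted p = 0.00697) and above background on 2 of 3 AACO arrays. Adgre1, which encodes the F4/80 antigen, changed by −1.50 ± 0.16 (adjusted p = 0.0083). The scavenger receptor gene Cd163 (−1.66), the complement genes C1qa (−1.18), C1qb (−1.20) and C1qc (−1.46), Cd14 (−1.10), Fcgr1a (−0.84) and Cd68 (−0.64), chosen after their values were seen, fell as well. Lyz2 (−0.81, adjusted p = 0.0766) passed only when adjusted over the list alone, Aif1 (−0.07) and Csf1r (0.04), all chosen after their values were seen, did not pass, and the other probe of Csf1r moved by −1.07. Of 12 markers tested 9 fell over all genes and 10 adjusted over the list alone. Their median was −1.14, and the list was lower in camera (adjusted p = 8.02e-08, but 0.557 with an estimated correlation, with which no list passed). Further genes of myeloid cells, chosen after their values were seen, fell too: Ms4a4a (−2.48), Fcgr2b (−1.94), Ctss (−1.69) and Clec10a (−1.66). They belong to none of the lists and were not tested as a set.

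Other immune genes moved less evenly. The chemokine genes Ccl2 (−1.41 ± 0.22, adjusted p = 0.0165) and Cxcl2 (−2.41 ± 0.39, adjusted p = 0.0192, above background on 1 of 3 AACO arrays) fell, as did Ccl7 (−1.37) and Il18 (−0.97), chosen after their values were seen. The cytokine gene Tnf went the other way, at 0.65 ± 0.13 (adjusted p = 0.0334), and Il6 was too dim to be tested. Of 19 inflammatory cytokines and NF-kappaB targets 1 rose and 4 fell, or 1 and 6 adjusted over the list alone, and the list was lower (median −0.51, adjusted p = 0.00915, but 0.557 with an estimated correlation and 0.0505 without control replicate 3, and called in 17 of 19 alternatives to the fit, over which the adjusted p ran from 4.28e-06 to 0.084). In the interferon response Rsad2 fell (−0.91 ± 0.21, adjusted p = 0.0439) and Isg15 did not pass (−0.72 ± 0.21, adjusted p = 0.0728). That list was lower with a median of −0.35 over 22 genes (adjusted p = 0.00779, but 0.654 with an estimated correlation, and called in 18 of 19 alternatives to the fit, over which the adjusted p ran from 0.000103 to 0.134), though 1 member fell over all genes and 0 adjusted over the list alone. Among neutrophil markers Retnlg fell (−1.60 ± 0.20, adjusted p = 0.0104) and S100a8 did not pass (−1.59 ± 0.40, adjusted p = 0.0524), and all 5 tested members fell adjusted over the list alone. The neutrophil list was lower (median −1.41, adjusted p = 0.00461, but 0.557 with an estimated correlation, and called in 18 of 19 alternatives to the fit, over which the adjusted p ran from 6e-09 to 0.084).

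Of 12 genes that respond to glucocorticoids 5 fell. Pdk4 changed by −2.08 ± 0.09 (adjusted p = 0.00216; chromosome 4, 30239150 to 30241038, rn4) and the metallothionein gene Mt2A by −1.91 ± 0.33 (adjusted p = 0.022). Zbtb16 (−1.26), Sgk1 (−1.21) and Fkbp5 (−0.74), chosen after their values were seen, also fell. Adjusted over the list alone 6 fell, and the list had a median of −0.79 (adjusted p = 0.000301, but 0.557 with an estimated correlation). Of its members, Pdk4, Per1 and Cdkn1a were also in other lists.

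Among antioxidant and NRF2 targets, Hmox1 and the cystine transporter gene Slc7a11 (−0.82 ± 0.12, adjusted p = 0.0136) fell, as did Gclc (−0.46, chosen after its values were seen). Slc7a11 was above background on 1 of 3 AACO and 2 of 3 control arrays. Of 18 such genes 3 fell, or 5 adjusted over the list alone, with a median of −0.16. The list was lower (adjusted p = 0.0194, but 0.557 with an estimated correlation, 0.0598 without control replicate 1 and 0.0569 without control replicate 2). It was called in 12 of 19 alternatives to the fit, over which the adjusted p ran from 0.0119 to 0.205. Among heat shock proteins Hsp90aa1 fell (−0.69 ± 0.16, adjusted p = 0.0408) and Hspb1 did not pass (−0.67 ± 0.17, adjusted p = 0.0525). Of 12 heat shock proteins 1 fell, or 6 adjusted over the list alone, and the list was lower (median −0.28, adjusted p = 0.0219, but 0.557 with an estimated correlation, 0.0732 without AACO replicate 1 and 0.0913 without control replicate 2). It was called in 13 of 19 alternatives to the fit, over which the adjusted p ran from 0.0119 to 0.219. In the unfolded protein response Trib3 (−0.76 ± 0.09, adjusted p = 0.0103), Asns (−0.70 ± 0.12, adjusted p = 0.0232) and Atf4 (−0.51, chosen after its values were seen) fell, while the list as a whole did not differ (adjusted p = 0.6). Its median was 0.12 and its mean −0.04.

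Of the hypertrophy and fetal genes 10 of 14 were lower, but few passed the test. Nppb had a log2 fold change of −1.59 ± 0.61, with a spread of 1.28 (SD, n = 3) among the AACO arrays and 0.31 (n = 3) among the control arrays, and did not pass after adjustment. Its limma adjusted p was 0.138, and it differed in 2 of 19 alternatives. Nppa (−1.01 ± 0.92, adjusted p = 0.489), Acta1 (−0.61 ± 0.43, adjusted p = 0.369), Myh7 (0.05, adjusted p = 0.865), Myh6 (0.13, adjusted p = 0.619) and the calcium pump gene Atp2a2 (0.36, adjusted p = 0.455) did not pass. Myh6 and Myh7 had nearly the same signal on each array, at 7.65 and 7.61 on AACO replicate 1 and 7.06 and 7.11 on control replicate 1. These values may therefore say little about a shift between the myosin genes. The calcineurin regulator gene Rcan1 fell (−1.39 ± 0.27, adjusted p = 0.0286) and Mef2c rose (0.54 ± 0.10, adjusted p = 0.0285). They were the 2 of 14 hypertrophy and fetal genes that differed, also adjusted over the list alone. That list had a median of −0.42 (camera adjusted p = 0.159, but lower at 0.00339 without scaling and at 0.0416 with spike-in scaling), and fry's test for change in either direction gave an adjusted p of 0.00965. Among 20 sarcomere and calcium handling genes Cacna1c rose (0.54 ± 0.10, adjusted p = 0.0233, while its other probe moved by 0.07) and Hrc did not pass (0.28, adjusted p = 0.0866), with a list median of 0.14 (adjusted p = 0.311).

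Kcnh2 rose 2.60-fold (log2 1.38 ± 0.12, adjusted p = 0.00635), and its other probe moved by 0.91. Kcnj3 rose by 0.50 ± 0.11 (adjusted p = 0.0364), and Kcnj2, chosen after its values were seen, passed the test but was not well above background on any control array and too dim with AACO for its fold to be bounded. Of 17 ion channel and gap junction genes 3 rose, or 4 with 1 fall adjusted over the list alone (median 0.32, camera adjusted p = 0.311, and higher in fry at 0.0464). Among genes of matrix and fibrosis, Ccn2 fell 2.53-fold (log2 −1.34 ± 0.14, adjusted p = 0.00831) and the cross-linking enzyme gene Lox fell by 0.89 ± 0.17 (adjusted p = 0.0294). The collagen genes Col1a1 (0.18, adjusted p = 0.668) and Col3a1 (0.20, adjusted p = 0.682), Postn (−0.22, adjusted p = 0.865) and Tgfb1 (−0.41 ± 0.11, adjusted p = 0.0661) did not pass. The list of 24 genes, 2 of which fell, was lower (median −0.30, adjusted p = 0.0183, but 0.654 with an estimated correlation). That call was lost without AACO replicate 2 (0.055), without AACO replicate 3 (0.0522) and without control replicate 3 (0.273), and was kept in 14 of 19 alternatives to the fit, over which the adjusted p ran from 0.00121 to 0.273.

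Among genes of fatty acid use, Pdk4, Ucp3 (−1.32 ± 0.15, adjusted p = 0.00974) and Angptl4 (−2.14 ± 0.34, adjusted p = 0.0176, chosen after its values were seen) fell. The other 20 of 23 did not pass after adjustment, and the list had a median of −0.03 (camera adjusted p = 0.188). No gene of the 17 of glycolysis or the 20 of oxidative phosphorylation differed in limma. Eno3 (0.61 ± 0.20, adjusted p = 0.0943) and Slc2a4 (0.29, adjusted p = 0.0981) stood nearest in glycolysis (median 0.16, camera adjusted p = 0.311). Atp5po (0.27, adjusted p = 0.11) and Cox5a (0.59 ± 0.22, adjusted p = 0.133) stood nearest in oxidative phosphorylation, whose median was 0.01 while camera ranked it lower (adjusted p = 0.944).

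Clock genes moved in both directions. Dbp rose by 1.52 ± 0.21 (adjusted p = 0.0123), and its other probes moved by 1.70 and 1.89. It did not pass without AACO replicate 1 (adjusted p = 0.0547) or AACO replicate 2 (adjusted p = 0.0622). Ciart (1.44), Tef (0.80) and Bhlhe41 (2.35) rose and Npas2 (−0.91) fell, all chosen after their values were seen, and Bhlhe41 was above background on 1 of 3 control arrays. Of 16 clock genes 4 rose and 2 fell, or 6 and 3 adjusted over the list alone. The list had no common direction (median 0.16, camera adjusted p = 0.349), and fry's test for change in either direction gave an adjusted p of 0.000657.

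**Figure D2:**
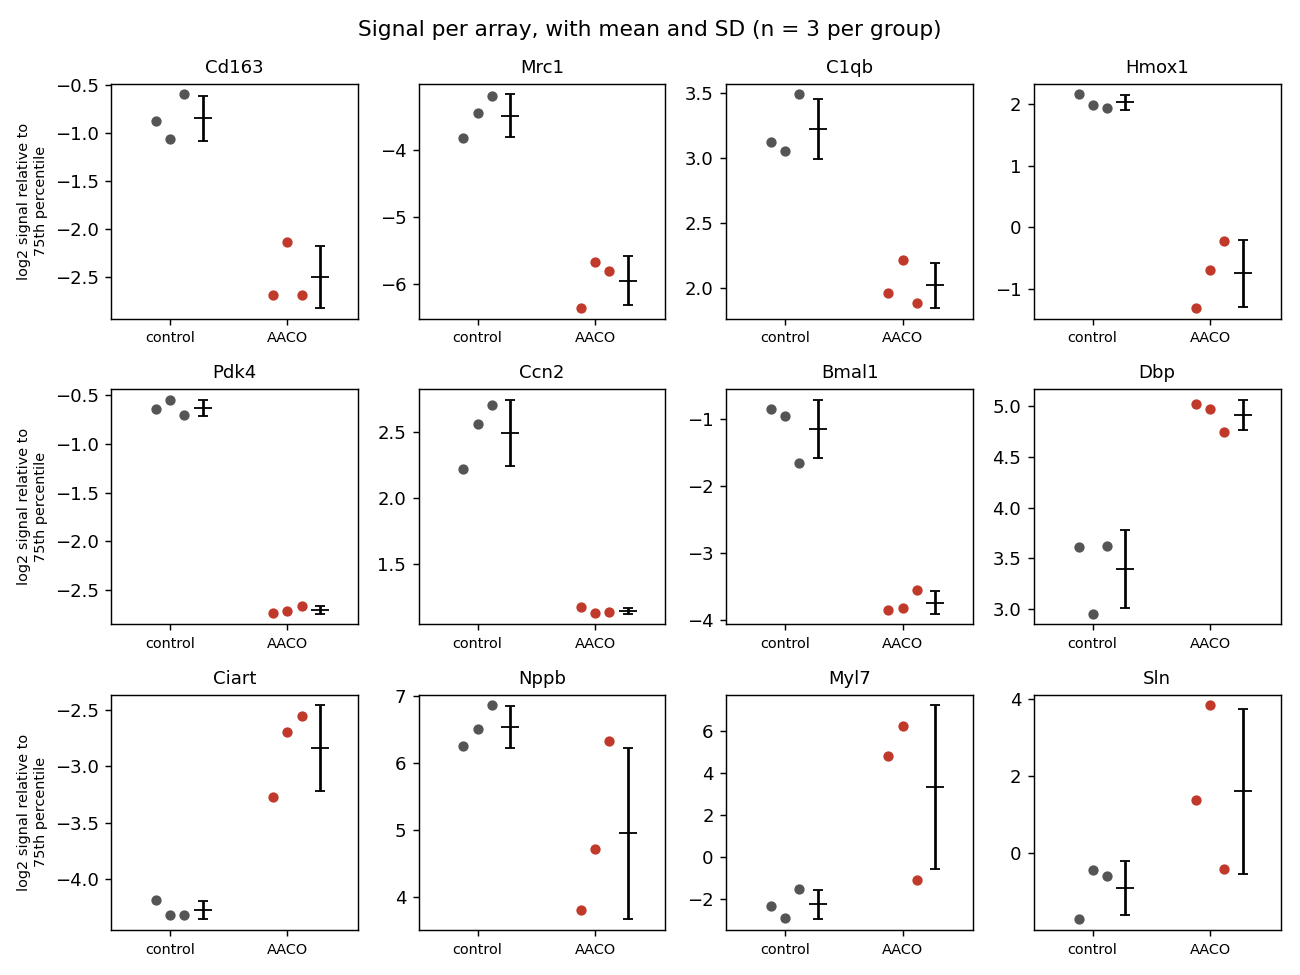
Normalized log2 signal (vertical axis) of 12 genes on each of the 3 AACO and 3 control arrays, with group means ± SD. The AACO values of Hmox1, Pdk4 and Mrc1 lie below all control values, and those of Myl7 and Sln are high on AACO replicates 1 and 2.

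Among signalling genes, the adrenergic receptor gene Adra1b rose by 0.84 ± 0.16 (adjusted p = 0.026). In the hypoxia list, adrenomedullin (Adm, −1.47 ± 0.14, adjusted p = 0.00719) and Bnip3 (−0.73 ± 0.13, adjusted p = 0.0243) fell. Adjusted over the list alone 2 fell and 2 rose, the latter Angpt1 (2.21, adjusted p = 0.0503 over all genes) and Epas1 (0.82), chosen after their values were seen. The hypoxia median was −0.19 (camera adjusted p = 0.0822, and lower in fry at 0.0437). The growth gene Myc fell by 1.81 ± 0.24 (adjusted p = 0.0119), and with Nr4a3 it was 1 of 2 immediate early genes of 20 that fell, with 1 rise and 2 falls adjusted over the list alone (median 0.19, mean −0.08, camera adjusted p = 0.561, but lower at 0.0459 without AACO replicate 2 and at 0.0145 with the Myl7 and Sln level as a covariate). Gadd45b (−0.87 ± 0.15, adjusted p = 0.0227) and Bcl2l1 (−0.66 ± 0.15, adjusted p = 0.0404) fell and Bcl2 (1.31, chosen after its values were seen) rose among 16 apoptosis and p53 genes (median −0.17, camera adjusted p = 0.235). In the cell cycle list Mcm2 rose (0.73 ± 0.15, adjusted p = 0.0352) and Ube2c did not pass (−0.45, adjusted p = 0.133), with a median of −0.14 (camera adjusted p = 0.555).

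Among markers of other cell types of the heart, single endothelial, smooth muscle and T cell genes differed. No fibroblast marker differed, with Dcn at −0.57 (adjusted p = 0.148) and Fbln1 at −0.61 (adjusted p = 0.176; list median −0.43, camera adjusted p = 0.207, but lower in 3 of 19 alternatives, at 0.0148 without AACO replicate 2 and at 1.87e-05 with the Myl7 and Sln level as a covariate). The endothelial gene Fabp4 fell (−0.66 ± 0.16, adjusted p = 0.0464) and Kdr did not pass (−0.36, adjusted p = 0.0895). The endothelial list was lower (median −0.30, adjusted p = 0.0108, but 0.557 with an estimated correlation, and lower in 15 of 19 alternatives to the fit, over which the adjusted p ran from 0.0108 to 0.134). Smtn of smooth muscle rose (0.57 ± 0.12, adjusted p = 0.0322) and Myh11 did not pass (0.60, adjusted p = 0.0728; list median 0.28, camera adjusted p = 0.28). Cd4 fell (−1.05 ± 0.17, adjusted p = 0.0189), while Nkg7 (0.37, adjusted p = 0.395) and the T and NK cell list (median 0.17, camera adjusted p = 0.984) did not differ. Of B cell markers, 2 were bright enough to test, and neither Fcrla (1.28, adjusted p = 0.11) nor Pax5 (−0.35, adjusted p = 0.221) differed.

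Of 6 red cell genes tested 3 fell. Alas2 (−1.33 ± 0.24, adjusted p = 0.0243), Ahsp (−1.47 ± 0.27, adjusted p = 0.0252) and Hbb-b1 (−0.88, chosen after its values were seen) fell, while Hba-a1 (−0.24) and Hbb (0.05), also chosen afterwards, did not pass. The erythroid list had a median of −0.62 over 6 genes (adjusted p = 0.0183, but 0.557 with an estimated correlation, and lower in 16 of 19 alternatives to the fit, over which the adjusted p ran from 0.000789 to 0.133). The platelet gene Pf4 fell (−0.97 ± 0.13, adjusted p = 0.0119), and Treml1 (−0.61, adjusted p = 0.17) and the platelet list (median −0.34, camera adjusted p = 0.273) did not pass. Of mast cell genes, neither Mcpt1 (−0.51, adjusted p = 0.0717) nor Kit (0.68, adjusted p = 0.0761) differed over all genes, though adjusted over the list alone 1 rose and 1 fell (list median −0.02, mean 0.05, camera adjusted p = 0.817). In fat, Cfd (−0.97, adjusted p = 0.115) and Pnpla2 (−0.42, adjusted p = 0.133) did not pass (adipocyte list median −0.23, camera adjusted p = 0.324, but lower at 0.047 without AACO replicate 2).

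The nerve and Schwann cell list was the only 1 of 36 lists called higher. Sox10 rose by 1.52 ± 0.35 (adjusted p = 0.045) and S100b did not pass (1.62 ± 0.56, adjusted p = 0.111). The list of 8 genes had a median of 0.99 (adjusted p = 0.0353, but 0.557 with an estimated correlation, 0.0748 without AACO replicate 1, 0.0598 without control replicate 1 and 0.0664 without control replicate 2). It was called in 14 of 19 alternatives to the fit, over which the adjusted p ran from 0.00103 to 0.314. With the Myl7 and Sln level as a covariate the list was not called higher. Its mean was 1.54, 1.44 and 0.48 on AACO replicates 1, 2 and 3 and between −0.24 and 0.28 on the control arrays. The atrial myosin gene Myl7 was high on the same arrays, at 4.83 and 6.26 on AACO replicates 1 and 2, −1.06 on AACO replicate 3 and −2.91 to −1.51 on the control arrays (log2 fold change 5.59 ± 1.80, limma adjusted p = 0.0954). Pam of the atrial list fell (−0.51 ± 0.11, adjusted p = 0.0404), and the list did not differ (median 0.46, camera adjusted p = 0.6).

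The remaining marker lists did not differ. In the mesothelium list Gpm6a rose (0.76 ± 0.18, adjusted p = 0.0493) and Wt1 did not pass (−0.33, adjusted p = 0.228; median −0.29, mean 0.05, camera adjusted p = 0.817). The skeletal muscle gene Myh4 passed the test (adjusted p = 0.0196) but was not well above background on any control array and too dim with AACO for its fold to be bounded, Atp2a1 did not pass (0.48, adjusted p = 0.0799), and the list had a median of 0.15 (camera adjusted p = 0.44). With normexp background correction the direction of Myh4 turned. The lung genes Ager (0.19, adjusted p = 0.246) and Sftpc (−0.56, adjusted p = 0.542), with a list median of −0.43 (camera adjusted p = 0.885), did not pass. Neither did the liver genes Tf (−0.85 ± 0.21, adjusted p = 0.0534) and Ttr (−0.56, adjusted p = 0.128; list median −0.56, camera adjusted p = 0.242). Adjusted over the list alone 2 of 3 liver genes fell. The thymus and lymph node genes Ltb (0.31, adjusted p = 0.17) and Cxcl13 (1.49 ± 0.96, adjusted p = 0.334) did not pass either (list median 0.31, camera adjusted p = 0.514).

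**Figure D3:**
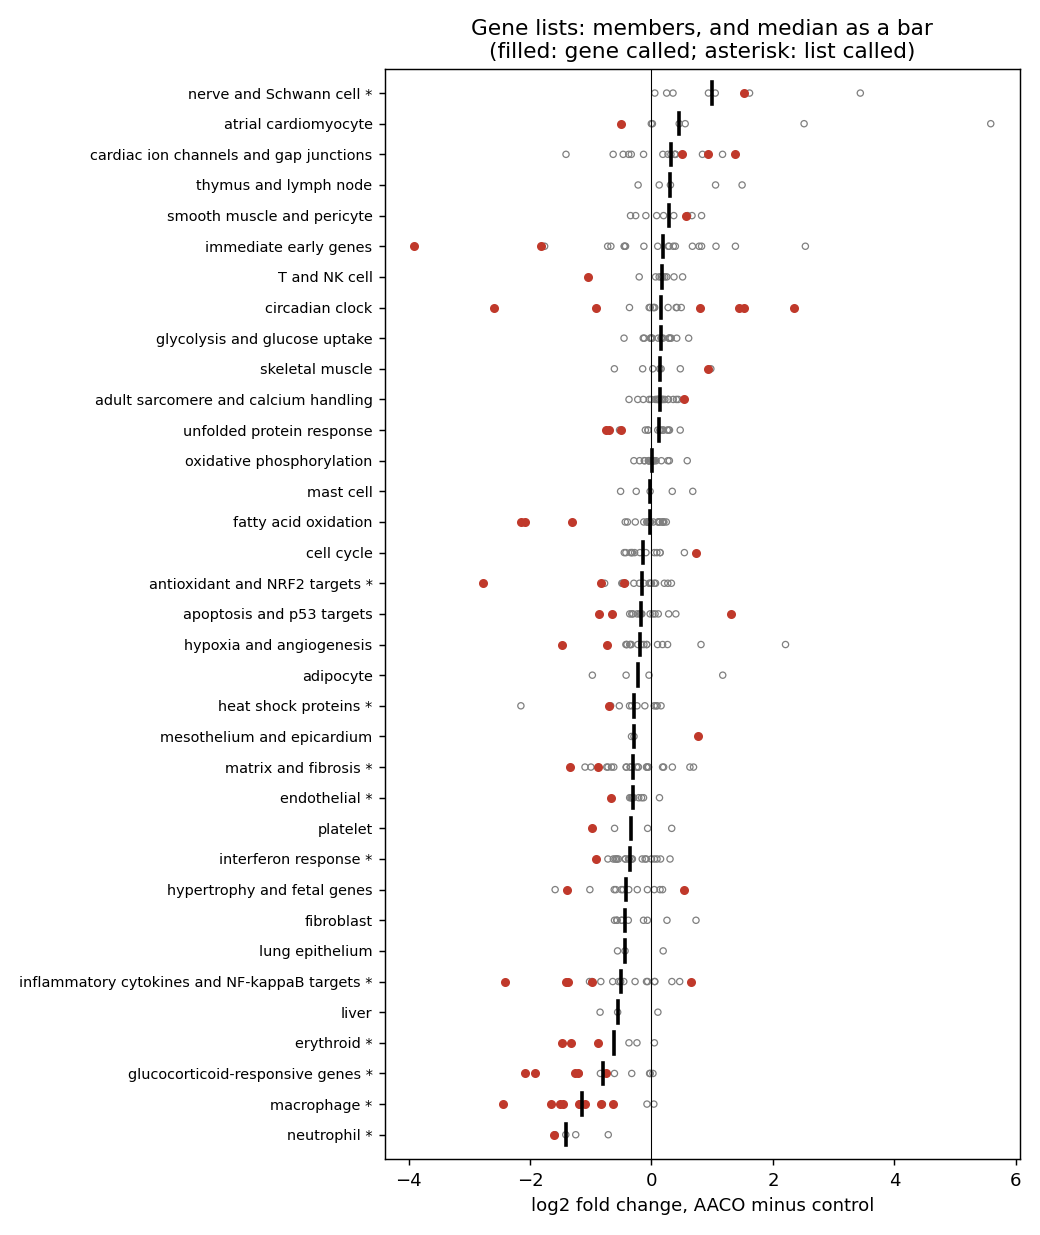
Log2 fold changes of AACO against control (horizontal axis) of the members of the lists tested, all but 1 of the 36, with a bar at each list's median. Filled points are genes that differed and an asterisk marks a list called by camera at the preset correlation: 1 list was higher and 10 were lower. With a correlation estimated for each list, 0 lists were called.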

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

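The counts of genes in other splits of the samples and the tests on slides, on blood, on other cell types and on the time of day were chosen after the results were seen, and the covariate tests after the levels of Myl7 and Sln were seen but before their fits were run.

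Of 96 synthetic control probes of the ERCC set, for which the labels mention no added RNA, 1 stood 1.3 higher on the log2 scale on the AACO arrays. Its normalized signal was −4.63 ± 0.49 (SD, n = 3) with AACO and −5.93 ± 0.31 (n = 3) in controls, and it drew attention as a signal outside the gene probes that was above its level in the control samples. Another probe stood 1.23 higher, but its AACO and control values overlapped, and 91 of the 96 were lower with AACO (median −0.62). The 75th percentile subtracted in scaling was 0.486 higher on the AACO arrays. By itself this lowers, with AACO, any probe whose unscaled signal was equal in both groups. No biological explanation was tested for the probe that stood 1.3 higher.

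With 3 against 3 samples there are 10 splits, too few for a share under 0.05. The real split gave 1975 genes and the highest of the others 0 (1 of 10 splits with as many). For genes at an unadjusted p under 0.05 with at least a 2-fold difference the real split gave 1029 and the highest of the others 158, again 1 of 10 splits with as many. For lists the real split gave 11 and the highest of the others 10, again 1 of 10 splits with as many, so an arbitrary split can call nearly as many lists at the preset correlation. Of the 2 slides, 0 held both groups, so an effect of slide or scan day cannot be told apart from AACO for any gene.

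Macrophage markers were lower with AACO, with a median of −1.14 over 12 genes, none of them in another list: Lyz2 went from a mean of 3.56 in control hearts to 2.75 with AACO and C1qb from 3.22 to 2.02. A lower share of every cell type other than cardiomyocytes would lower the markers of all of them alike, but the 40 fibroblast, endothelial, smooth muscle and T cell markers had a median of −0.111 (SD 0.43). Within these, medians were −0.43 for fibroblast and −0.30 for endothelial markers, against 0.28 for smooth muscle and 0.17 for T and NK cells. The types thus did not fall alike, but a lower share of fibroblasts or endothelial cells is not excluded. Atrial tissue in AACO replicates 1 and 2 would leave no difference once the level of Myl7 and Sln entered as a covariate, but the list stayed lower then (camera adjusted p = 8.78e-10, mean −1.22; 4.24e-14 to 5.61e-05 over the 19 alternatives that kept the test, but 0.557 with an estimated correlation in the fit without the covariate), though limma called 0 single genes with the covariate (2276 at unadjusted p under 0.05). Less blood in the AACO hearts stays open, since the erythroid median was −0.623 (SD 0.62, 6 genes) and lay within its members' spread of the macrophage median, and the abundant red cell genes Hba-a1 (−0.24, other probe −1.13) and Hbb (0.05, other probe −1.30) gave no single answer. Fewer macrophages, or less expression of these genes in them, under AACO may explain the pattern and was not tested, and neither can be told apart from slide and scan day.

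Clock genes moved apart, with Bmal1 and Npas2 lower and Dbp, Ciart, Tef and Bhlhe41 higher with AACO. Hearts collected at another time of day could give this: the 5 genes that peak with Bmal1 had a mean of −0.54 (median −0.04) and the 10 of opposite phase a mean of 0.70 (median 0.38; exact permutation over genes, p = 0.0336, 3003 permutations, and genes are not independent replicates). Yet 3 of the 5 and 9 of the 10 moved the predicted way, Cry1 (0.41) and Nfil3 (0.42), chosen after their values were seen, did not follow Bmal1, Bhlhe41 was above background on 1 of 3 control arrays, and a requirement on these shares, set after the p was seen, was not met, so the time of day stays open. Among those counted as moving, Clock (−0.04), Nr1d1 (0.04), Bhlhe40 (0.05) and Per3 (0.03) hardly moved. The other probes of Per3 moved by 0.94 and 1.15, so the arms depend on the choice of probe. With the level of Myl7 and Sln as a covariate the difference between the arms went from −1.24 to −1.07 (exact permutation p = 0.0506), so the covariate removed little of it, and atrial tissue was neither borne out nor excluded. An effect of AACO on the clock was not tested, and the labels give no time of day.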

How the results depend on the processing

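The spike-in scaling, the Myl7 and Sln covariate and the fit without AACO replicates 1 and 2 were chosen after seeing the data, and the other alternatives were planned. Quantile normalization, median scaling, the series matrix, the mean of the probes of a gene and eBayes with trend and robust left the counts of genes called higher in AACO or genes called lower in AACO, of genes with unadjusted p under 0.05 and at least 2-fold higher (or genes with unadjusted p under 0.05 and at least 2-fold lower), and of gene lists called higher or lower within 1.5 times the main counts. With no scaling between arrays, 5493 genes were called higher and 232 lower, and 2281 and 101 at unadjusted p and 2-fold. Normexp background correction gave 1528 called lower, 228 and 186 at 2-fold, and 4 gene lists called higher and 6 lower. With no filter on dim probes, and so 26310 genes tested, 1401 were called lower, 892 were 2-fold lower and 2 gene lists were called lower. Requiring a signal well above background on all 6 arrays, which tested 15522 genes, left 395 at 2-fold higher. Array weights gave 1786 called higher and 1325 lower, and spike-in scaling 505 lower. Without AACO replicates 1 and 2, a fit that takes the lone AACO sample to vary like the controls, limma called 0 genes higher and 0 lower (2216 at unadjusted p under 0.05), 278 were 2-fold higher and 0 gene lists were called higher. With the Myl7 and Sln covariate it called 0 and 0 (2276 at unadjusted p under 0.05), 310 were 2-fold higher and 0 gene lists were called higher. The fit without AACO replicates 1 and 2 and the covariate fit have fewer degrees of freedom than the main fit. The covariate fit has as many as the fits without 1 array, and those called genes. Lost degrees of freedom alone thus do not account for the lack of calls with the covariate. The Myl7 and Sln level was also high on AACO replicates 1 and 2 and so overlaps with group. The cause was not tested for any of the alternatives. Leaving out 1 array at a time, genes called higher ranged from 108 to 1225, genes called lower from 148 to 937, and gene lists called higher from 0 to 1. With an estimated inter-gene correlation 0 gene lists were called higher and 0 lower (1 of 36, the endothelial list, at unadjusted p under 0.05, against 12 at the preset one), fry's directional test called 1 higher and 4 lower, and its mixed test, which has no direction, called 27, of which camera placed 10 higher and 17 lower. Of the 56 named genes that differed, 1049 of 1050 results under alternatives kept their sign and 744 stayed called. The exception was Myh4, a probe near background, at −0.21 with normexp (adjusted p = 0.421). The macrophage and glucocorticoid lists stayed called in 19 of 19 alternatives other than the change of set test. The slide and scan date could not enter as blocks, since each slide and day held 1 group. No paired analysis was possible because the groups share no replicate number in the labels. Signal over background limits the genes measured in 1 group alone: 116 that rose were not above background on any control array, and 11 that fell on any AACO array. The AACO arrays had more spots well above background (71.79% against 67.45%), which bears on this imbalance and was not separated from it.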

Other observations

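The scan of gene families and the choice of the genes below followed the sight of the data. Sln, like Myl7 a transcript of the atria, was 1.39 and 3.85 on AACO replicates 1 and 2, −0.41 on AACO replicate 3 and −1.71 to −0.42 on the control arrays. Myl4 was level (−0.00, limma adjusted p = 0.992). It read 6.63 to 6.94 on every array, also on the control arrays where Myl7 was low. Its values may therefore say little about atrial tissue. Nppb was 3.81, 4.73 and 6.33 on AACO replicates 1, 2 and 3 and 6.25 to 6.87 on the control arrays. Nppa did not follow Myl7, at 2.80, 5.49 and 5.86 on AACO replicates 1, 2 and 3 and 4.95 to 6.99 on the control arrays.

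Among 212 gene families by name, tested in both directions, 31 of 186 zinc finger genes named Zfp rose (16.7% against 4.30% of other named genes, adjusted p = 8.37e-08, Fisher's exact test), and 18 of 132 olfactory receptor genes fell (13.6% against 4.93%, adjusted p = 0.022). These tests and that of the probe ID features below count genes as independent, though all come from the same 6 arrays. Their p-values therefore do not measure the spread between samples. The olfactory receptor median was −0.30, and 0.19 without scaling, where the median of all genes was 0.52. When a signal well above background was required on all 6 arrays, 74 of the 132 were left, of which 15 fell and 1 rose (median −0.28). Many of the 132 thus lay near background, and what this does to their falls was not tested. The Zfp median was 0.25, and 0.06 with normexp, where the median of all genes was −0.07. Of 8 Kcnj genes 4 rose (adjusted p = 0.0342), and of 8 Ms4a genes 4 fell (adjusted p = 0.0397) and 1 rose. These counts leaned on single arrays: Zfp rises numbered 5 without AACO replicate 1, 3 without AACO replicate 2, 36 without AACO replicate 3, and 15, 13 and 9 without control replicates 1, 2 and 3. Olfactory receptor falls numbered 6 without AACO replicate 1, 2 without AACO replicate 2 and 10 without control replicate 3, but 28 with array weights and 49 with normexp, and without scaling 16 rose and 5 fell. Kcnj rises numbered 0 to 3 over the 6 fits without 1 array, and Ms4a falls 2 to 4. Of 2297 features with only a probe ID, 297 rose (12.9% against 5.32%, exact p = 1.4e-36) and 102 fell (35 rises without AACO replicate 2, 58 without AACO replicate 1 and 104 without control replicate 3), with a median of 0.17, and of −0.0006 with normexp.

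Other large changes outside the lists were those of Tent5a (−2.19 ± 0.09, adjusted p = 0.00216), the growth factor gene Gdf15 (−2.39 ± 0.30, adjusted p = 0.0112), the transferrin receptor gene Tfrc (1.71 ± 0.18, adjusted p = 0.0083) and Igfbp7 (1.84 ± 0.27, adjusted p = 0.0142), all by limma. Ms4a6a was not above background on any AACO array and was at least 3.03-fold lower (adjusted p = 0.0069). The 8 Agilent spike-in probes above background on all arrays differed between the groups by a median of −0.09 after scaling, from −0.20 to 0.39. The slope of log2 signal along transcripts, relative to the mean array, ranged from −0.0155 to 0.0218 per kb on the AACO arrays and from −0.00424 to 0.00379 on the control arrays (2026 transcripts).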
